A study of Mus musculus with 6 samples.

How the data were processed

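Splenic T cells of 6 mouse recipients of bone marrow were profiled, 3 treated with PBS and 3 with rapamycin at 1.5 mg/kg, each on 1 array. Group and replicate number were taken from the sample titles, which call the samples biological replicates, and the series' design text speaks of 3 mice per group. Per the labels' protocols, spleens were taken on day 10 after transplantation, cells were stained for CD3 and sorted by flow cytometry, total RNA was extracted with Trizol, and it was labelled with a whole-transcript sense target assay. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA. The versions, the summary level and the probe library files are not given in the sources used here.

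The deposited values are log2 expression after RMA, which subtracts background, gives all arrays the same distribution of probe intensities and summarises the probes of each probe set. These steps remove any shift shared by most genes of an array, so a general change in RNA content per cell would not be seen, and values near background are compressed, which makes differences of weakly expressed genes look smaller. The file held 35556 probe sets per array. Array medians lay between 6.03 and 6.17 and maxima between 14.2 and 14.3. Detection calls were not used here.

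Genes were named through the platform's probe table. It listed 23410 of the probe sets, 21789 with exactly 1 gene symbol and 1621 with several, and 12146 were not listed and stay unnamed. For 21698 of the probe sets with 1 symbol the gene identifier was found in a RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. Coordinates were not used, because the array's genome build is not given in the sources used here. Each gene was represented by its probe set with the highest mean over all 6 arrays, giving 19938 genes. In 352 of the 999 genes with 2 or more probe sets, the probe sets differed in the direction of the group difference. The 13767 probe sets that were not listed or had several symbols were tested separately with limma: 0 passed an adjusted p of 0.05, and 453 had an unadjusted p under 0.05. Further probe sets of the named genes were not part of that test.

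Gene differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over the 19938 genes and a call at an adjusted p under 0.05 with no fold limit. The moderated test had 8.44 degrees of freedom. Intervals are at the 95% level. All p values of single genes and lists are two-sided and come from these models across all genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

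A total of 37 gene lists were fixed before the data were examined, from general knowledge of T cells, mTOR signalling and the other cells of a spleen after transplantation, and 11 of these lists are markers of cells other than T cells. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over the 37 lists. Beside it stand camera with a correlation estimated from the arrays and fry. Adjusted p values of lists are those of camera with the preset correlation unless another is named.

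The genes named were chosen by a rule fixed before the data were examined. It takes genes past the threshold whose groups do not overlap, up to 12 a direction, and where fewer pass, those with the smallest p in that direction up to 6. From each list it takes up to 4 members past the threshold, or the members with the smallest p up to 2. It adds Ptprc, Cd3e, Cd4, Cd8a, Foxp3 and Mtor, the 4 genes with the smallest p in each direction and up to 4 lead genes a side of each principal component described. Members that passed adjusted over the list alone, Lcn2, Cd79a and Ms4a1, and Cd36, Plxdc2 and Exph5 among the calls without rapamycin replicate 1, were named outside this rule after their values were seen.

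The gene test was checked on simulated data: in 20 simulations with the spread of these arrays over 19938 genes, 200 genes each were given known differences. It recovered 62.3% of 1.5-fold changes, 94.9% of 2-fold changes and 99.1% of 3-fold changes, and 5% of its calls were false. With 200 changed genes the adjusted threshold is easier to reach than where few genes pass, so these shares may overstate recovery here. The simulated genes were drawn independently of each other from normal distributions, with variances from the fitted model. Variation shared by many genes, as in the real arrays, was not simulated, so the share of false calls under it is not known. In the real data 12 genes had an absolute difference of 1 log2 or more, and 1 gene passed. The set test was checked on simulated lists of 25 genes. With the preset correlation it called 100% of lists shifted by 0.15 log2 and 33.8% of unshifted lists whose members shared a correlation of 0.3. With the estimated correlation these were 75.5% and 0.5%. The shifted lists had independent members. Lists that were both shifted and correlated were not simulated, so the share of such lists that would be called is not known.

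Alternatives listed before the data were examined were leaving out each mouse in turn, the replicate number as a block, quantile normalization applied again, median centring of arrays, leaving out the lowest 30% or 50% of genes by mean, an intensity trend with robust variance, array weights, the mean of a gene's probe sets, every probe set tested separately, a plain equal-variance test per gene and other thresholds. A granulocyte score per array, the mean of the measured neutrophil and granulocytic precursor genes, was added as a covariate after the data were examined.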

Results

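RNA of splenic T cells from 6 mice was measured on whole-transcript expression arrays, 1 array per mouse. The mice were B6D2F1 animals, an F1 hybrid that carries a B6 parental genome, and they had been lethally irradiated and given T cell-depleted B6 bone marrow. The protocol covers recipients with and without added B6 spleen cells, and the labels do not state which applies to each mouse. Rapamycin, an inhibitor of the kinase mTOR, was injected at 1.5 mg/kg every other day until day 10 in 3 mice, and 3 mice received phosphate-buffered saline (PBS) in its place. CD3-positive cells were sorted from the spleen on day 10. Values are log2 expression, so a difference of -1 is a level lower by a factor of 2, and all differences are rapamycin minus PBS. The number of arrays, 3 per group, limits the precision: the median standard error of a difference over 19938 genes was 0.0955 log2.

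The comparison asked which transcripts of splenic T cells differ when the recipient receives rapamycin. Glp1r, which encodes the receptor for the incretin hormone glucagon-like peptide, was lower with rapamycin and was the only gene of 19938 that passed the test. Its level was 8.28 ± 0.09 with PBS and 7.04 ± 0.15 with rapamycin (log2, SD, n = 3 each), a 2.37-fold lower level, and every rapamycin mouse lay below every PBS mouse. The log2 difference was -1.24 (SE 0.10, 95% interval -1.47 to -1.02), with an adjusted p of 0.0174 in limma's moderated test. Several gene lists shifted by small amounts under a set test with a preset correlation, which did not hold with an estimated one. Among them homing and adhesion and fatty acid synthesis genes lay lower, with list means per mouse that did not overlap between the groups. No other list of the 37 separated in this way, and chance alone gives 10% for 3 against 3 mice. The separation is therefore no support by itself. Sterol and mitosis genes lay lower and glycolysis, ribosome biogenesis and neutrophil genes higher, but their list means per mouse overlapped between the groups.

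**Figure D1:**
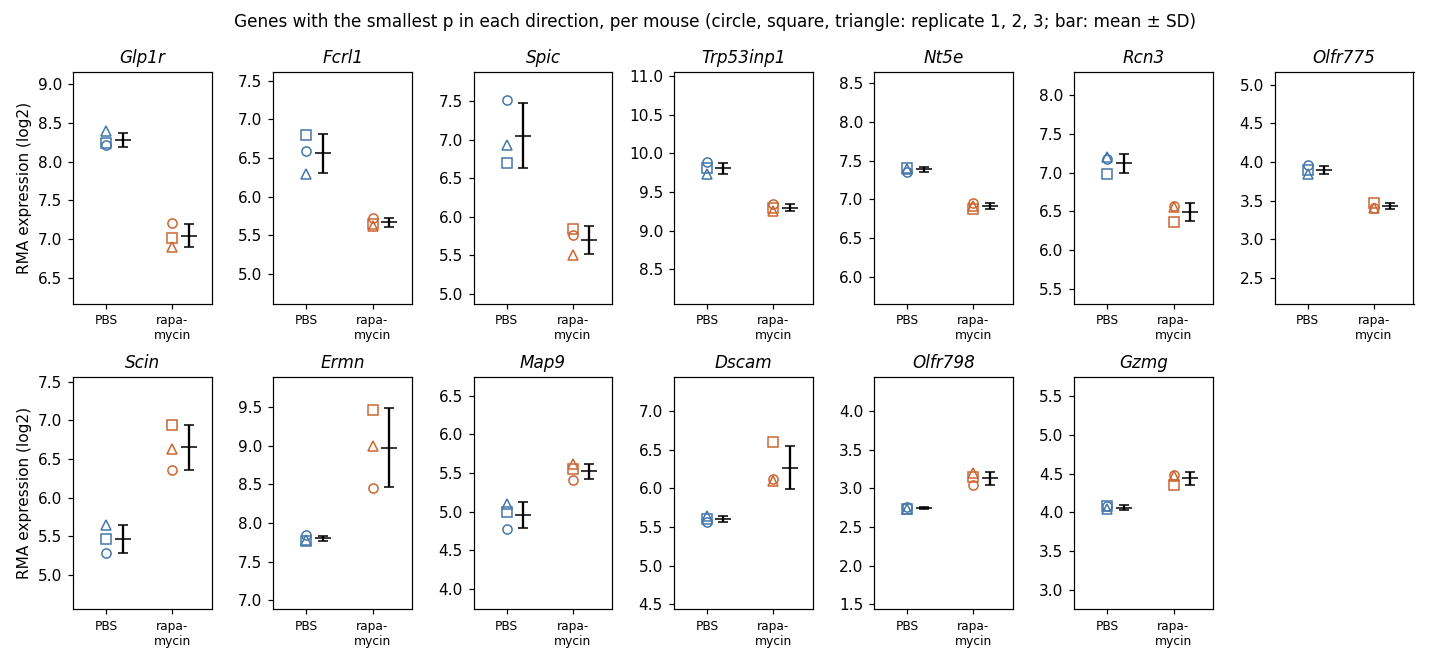
RMA expression (log2, y axis) of the genes with the smallest p in each direction, for each of the 3 PBS and 3 rapamycin mice (x axis), with the mean ± SD as bars; the upper row holds genes lower with rapamycin and the lower row genes higher with it. Glp1r, at 8.28 with PBS and 7.04 with rapamycin, is the only one that passed the adjusted test, and in all 13 genes the groups do not overlap.

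No gene passed in the upward direction. Of the 932 genes at an unadjusted p under 0.05, 319 were higher and 613 lower with rapamycin, which is 4.67% of the genes tested. The groups did not overlap for 1878 genes, or 9.42%, where chance gives 10%. Differences were small throughout: 91.1% of genes lay within 0.2 log2 of no difference, and 12 genes reached an absolute difference of 1 or more. The Glp1r call was lost when any mouse other than rapamycin replicate 1 was left out, with adjusted p of 0.0858 to 0.214, against 0.0153 without rapamycin replicate 1 and 0.00505 to 0.376 over 16 alternatives. The log2 difference itself lay between -1.33 and -1.18 in all 16. Without rapamycin replicate 1, 7 genes passed in place of 1: Glp1r lower, and Scin, Ermn, Cd36, Plxdc2, Gzmf and Exph5 higher.

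Among genes that did not pass, the next smallest p values belonged to genes of several functions. Scin, an actin-severing protein, measured 5.47 ± 0.18 with PBS and 6.65 ± 0.29 with rapamycin, a difference of 1.18 (SE 0.15, adjusted p = 0.382). Ermn, a cytoskeletal protein of myelin-forming cells, had a difference of 1.17 (SE 0.21), Map9, a microtubule-associated protein, 0.57, and Dscam, a cell adhesion molecule, 0.67. Olfr798, an olfactory receptor, measured 0.38 higher (2.75 with PBS and 3.13 with rapamycin), and the granzyme Gzmg 0.37 higher (4.06 and 4.44). Both lay low against array medians of 6.03 to 6.17, and whether they were detected was not tested. In the other direction, Spic, a transcription factor of splenic red pulp macrophages, measured 7.05 ± 0.42 with PBS and 5.70 ± 0.18 with rapamycin, a difference of -1.34 (SE 0.19, adjusted p = 0.408). Fcrl1, an Fc receptor-like protein of B cells, had a difference of -0.89 (SE 0.13). Trp53inp1, a p53-induced regulator of autophagy and cell death, had -0.51, Nt5e, the ecto-enzyme that makes adenosine, -0.47, the endoplasmic reticulum protein Rcn3 -0.63 and Olfr775 -0.47, each at an adjusted p of 0.408. Olfr775 also lay low, at 3.90 with PBS and 3.43 with rapamycin. Since Glp1r belongs to none of the 37 gene lists, no list member passed over all genes, and members named below are given by their values.

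Identity genes of the sorted population lay close between the groups. Cd3e measured 12.87 ± 0.05 with PBS and 12.84 ± 0.08 with rapamycin, and the pan-leukocyte gene Ptprc differed by -0.09 (SE 0.07). Cd4 differed by 0.14 (SE 0.20), Cd8a by 0.03 (SE 0.09), and Foxp3, the regulatory T cell factor, by -0.30 (SE 0.17). Mtor, whose product rapamycin inhibits as part of a complex, differed by -0.07 (SE 0.10). Of the 16 measured genes of the T cell receptor complex and T cell identity, 12 had negative differences, with Cd5 at -0.19 and Cd28 at -0.14 (list adjusted p = 0.489). The CD4 lineage list (6 genes, median 0.12, adjusted p = 0.294) held Tnfrsf4 at 0.39 and Gata3 at -0.12. The CD8 lineage list (6 genes, median -0.15, adjusted p = 0.184) held Crtam at -0.27 and Cd8b1 at -0.13. Of both lineage lists and the identity list, 0 members passed when adjusted over the list alone.

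T cell homing and adhesion genes were lower as a group with rapamycin. Of 23 measured members 19 had negative differences, and the median was -0.15. The list mean of the rapamycin mice lay 0.14 to 0.22 log2 below the PBS mean, and no PBS mouse lay more than 0.03 from it. The set test with a preset correlation gave an adjusted p of 5.52e-05, and the list had an adjusted p of 0.248 with an estimated correlation. Itga1, the alpha-1 integrin that binds collagen, measured 8.38 ± 0.20 with PBS and 7.77 ± 0.24 with rapamycin, and S1pr5, a sphingosine-1-phosphate receptor used for egress, 6.55 ± 0.12 and 5.95 ± 0.21. Adjusted over the list alone, 3 members passed, namely Itga1, S1pr1 and S1pr5.

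Naive and quiescent T cell genes were also lower as a group, with 16 of 20 measured members negative, a median of -0.16 and an adjusted p of 0.0183, which became an adjusted p of 0.882 with an estimated correlation. S1pr1, the receptor that lets T cells leave lymphoid organs, had a difference of -0.46 (SE 0.11), and Tgfbr2, a receptor for TGF-beta, -0.32 (SE 0.09). Satb1, a chromatin organiser of T cells, went the other way at 0.40 (SE 0.11). These 3 members passed when adjusted over the list alone. The call ended when PBS replicate 1 or rapamycin replicate 3 was left out.

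The effector lists did not pass the set test. Cytotoxic effector genes (28 measured, 19 negative, adjusted p = 0.489) held S1pr5 at -0.59 and Gzmc at 0.53 (SE 0.12), and adjusted over the list alone 3 members passed, Gzmc, Gzmf and S1pr5. The list's median was -0.07 and its mean 0.02, which differ in sign. T cell cytokines and chemokines (21 measured, 12 positive, adjusted p = 0.489) held Csf2, encoding GM-CSF, at 0.70 (SE 0.25) and Il21 at 0.86 (SE 0.42). Among inhibitory receptors and exhaustion genes (19 measured, 11 positive, adjusted p = 0.646), Nt5e passed adjusted over the list alone, and the exhaustion factor Tox had a difference of -0.26 (SE 0.07). Regulatory T cell genes (19 measured, 9 positive, adjusted p = 0.813) held Il2ra, the IL-2 receptor alpha chain, at 0.37 and Tnfrsf1b at -0.22. Co-stimulatory receptors (18 measured, 7 positive, adjusted p = 0.830) held Cd70 at 0.47 (SE 0.12) and Tnfsf14 at -0.32 (SE 0.11). Gamma-delta and innate-like genes (9 measured, 5 positive, adjusted p = 0.509) held Il23r at 0.46 and Zbtb16 at -0.21.

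Cytokine receptor and STAT signalling genes were higher as a group. Of 23 measured IL-2, IL-12 and STAT genes, 14 had positive differences, with a median of 0.06 and an adjusted p of 0.0110, against an adjusted p of 0.882 with an estimated correlation. Il12rb2, the signalling chain of the IL-12 receptor, measured 10.45 ± 0.09 with PBS and 11.18 ± 0.41 with rapamycin. Adjusted over the list alone 0 members passed, and rapamycin replicate 2 had the highest list mean, 0.27 above PBS, where replicates 1 and 3 lay at -0.04 and 0.04. The call ended without PBS replicate 1, PBS replicate 2 or rapamycin replicate 2. Interferon-stimulated genes (33 measured, 20 negative, adjusted p = 0.839) held Ifit3 at -0.65 (SE 0.20) and Gbp5 at 0.31 (SE 0.14). The mean difference of this list was -0.05. It was 0.06 and called higher without rapamycin replicate 1 (adjusted p = 0.0272), and it was called lower without PBS replicate 2 (-0.14, adjusted p = 0.00415) or rapamycin replicate 2 (-0.18, adjusted p = 0.000194).

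Lipid synthesis genes were lower as groups. In fatty acid synthesis 14 of 15 measured genes had negative differences, with a median of -0.12 and an adjusted p of 0.000281, against an adjusted p of 0.323 with an estimated correlation. Scd2, a stearoyl-CoA desaturase, measured 10.38 ± 0.14 with PBS and 10.02 ± 0.04 with rapamycin, and the desaturase Fads1 8.50 ± 0.09 and 8.09 ± 0.16. Both passed when adjusted over the list alone. In sterol biosynthesis 17 of 20 measured genes were negative (median -0.12, adjusted p = 0.00372, and adjusted p = 0.882 with an estimated correlation), with 0 members passing adjusted over the list alone. Mvd of the mevalonate pathway had a difference of -0.31 (SE 0.12) and Srebf2, the regulator of sterol genes, -0.21 (SE 0.08). The sterol call ended without PBS replicate 3, rapamycin replicate 1 or rapamycin replicate 2, with array weights, and with the granulocyte score as a covariate (adjusted p = 0.135).

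Glycolysis and HIF-1 target genes were higher as a group, with 20 of 22 measured members positive and a median of 0.13 (adjusted p = 2e-05, and adjusted p = 0.882 with an estimated correlation). Slc16a3, a lactate exporter, had a difference of 0.34 (SE 0.13) and Bnip3, a mitophagy gene induced in hypoxia, 0.52 (SE 0.24). Ribosome biogenesis genes were positive in 30 of 35 measured members (median 0.09, adjusted p = 0.000513, and adjusted p = 0.882 with an estimated correlation), with Myc at 0.39 (SE 0.17) and Tcof1 at -0.15 (SE 0.08). Cytosolic ribosomal protein genes were positive in 35 of 44 measured members (median 0.04, adjusted p = 0.00355, and adjusted p = 0.882 with an estimated correlation). Rps25 differed by 0.12 and Rpl14 by -0.13. In these 3 lists 0 members passed adjusted over the list alone. The ribosome biogenesis call ended without PBS replicate 1 or rapamycin replicate 2, and the ribosomal protein call without rapamycin replicate 2.

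Mitosis genes lay lower in every one of the 29 measured members, with a median of -0.09 and an adjusted p of 9.4e-05, against an adjusted p of 0.882 with an estimated correlation. Plk1, a mitotic kinase, differed by -0.23 (SE 0.09) and Hmmr, a spindle-associated protein, by -0.18 (SE 0.08), and 0 members passed adjusted over the list alone. The call ended without PBS replicate 1. DNA replication genes (29 measured, 16 negative, median -0.01, adjusted p = 0.833) held Ccne1 at -0.11 and Rrm2 at -0.10.

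Genes of the mTOR pathway itself were negative in 21 of 34 measured members, with a median of -0.05 (adjusted p = 0.0931). Castor1, an arginine sensor upstream of mTOR, measured 7.86 ± 0.03 with PBS and 7.56 ± 0.08 with rapamycin, and Sesn1, a leucine-pathway regulator, 7.62 ± 0.09 and 7.36 ± 0.05. ATF4 targets and amino acid supply genes (27 measured, 18 negative, adjusted p = 0.227) held Sesn2 at -0.27 and the serine synthesis enzyme Psph at -0.26. Autophagy and lysosome genes (37 measured, 22 positive, adjusted p = 0.311) held Gabarapl1 at 0.22 and Hexa at 0.19. Oxidative phosphorylation genes (50 measured, 28 negative, adjusted p = 0.938) held Uqcrc1 at -0.17 and Cox5b at -0.13. Apoptosis regulators (19 measured, 12 positive, adjusted p = 0.416) held Casp9 at -0.20 and Bid at -0.22. Tissue handling and stress genes (19 measured, 11 positive, adjusted p = 0.280) held Egr2 at 0.54 and Egr1 at 0.25. In these 6 lists 0 members passed adjusted over the list alone, and likewise for the DNA replication, interferon, cytokine, regulatory T cell, co-stimulatory and innate-like lists above.

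**Figure D2:**
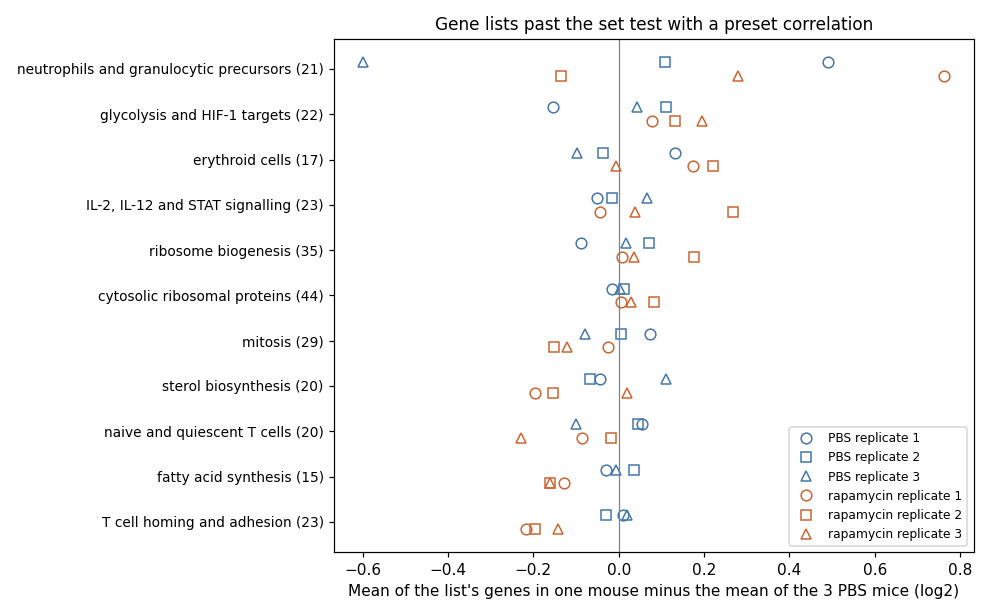
Mean of each list's measured genes in 1 mouse minus the mean of the 3 PBS mice (log2, x axis), for the 11 lists past the set test with a preset correlation (y axis, number of measured genes in brackets); blue symbols are PBS mice and orange symbols rapamycin mice, with circle, square and triangle for replicates 1, 2 and 3. The groups separate for homing and adhesion and for fatty acid synthesis, and overlap for the other lists shown, such as neutrophils, where PBS mice span -0.60 to 0.49. Chance alone gives such separation in 10% of lists, and no other list of the 37 tested separated.

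Markers of cells other than T cells were measured in every sorted sample. Neutrophil and granulocytic precursor genes were positive in 19 of 21 measured members (median 0.29, adjusted p = 0.000268, and adjusted p = 0.882 with an estimated correlation), and the list mean per mouse ranged from 7.89 to 8.98 with PBS and from 8.35 to 9.25 with rapamycin. Chil3, a secreted granulocyte and macrophage protein, differed by 0.62 (SE 0.25), and Elane, neutrophil elastase, by 0.61 (SE 0.30). Lcn2, a neutrophil granule protein, measured 12.20 ± 0.55 with PBS and 12.64 ± 0.27 with rapamycin. The neutrophil call ended without PBS replicate 3 or rapamycin replicate 1, with array weights, and with the granulocyte score, which is made of these genes. Erythroid genes were positive in 14 of 17 measured members (median 0.12, adjusted p = 0.00829, and adjusted p = 0.882 with an estimated correlation), with Epb42 at 0.31 and the transferrin receptor Tfrc, which dividing T cells also express, at 0.30. The erythroid call ended without any one of PBS replicates 2 and 3 and rapamycin replicates 1 and 2, with array weights, and without the lowest 50% of genes. In both lists 0 members passed adjusted over the list alone.

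The other cell type lists did not pass. Monocyte, macrophage and suppressor myeloid genes (23 measured, 12 negative, adjusted p = 0.489) held Spic, which passed adjusted over the list alone, and Ms4a7 at -0.26. B cell genes (18 measured, 10 positive, adjusted p = 0.839) held Cd79b, a B cell receptor subunit that measured 7.38 ± 0.21 with PBS and 6.84 ± 0.05 with rapamycin and passed adjusted over the list alone, and Fcmr at -0.12. Its partner gene Cd79a differed by -0.05 (SE 0.16) and Ms4a1 by 0.05 (SE 0.13). For the lists that follow, 0 members passed adjusted over the list alone. Natural killer cell genes (12 measured, adjusted p = 0.796) held Ncr1 at -0.24 and Itga2 at -0.65. Plasma cell genes (10 measured, adjusted p = 0.489) held Irf4 at 0.21 and Edem1 at 0.12. Dendritic cell genes (15 measured, adjusted p = 0.830) held Cst3 at 0.35 and Xcr1 at -0.22. Megakaryocyte and platelet genes (11 measured, adjusted p = 0.833) held Clec1b at -0.26 and Nrgn at 0.20. Mast cell and basophil genes (11 measured, adjusted p = 0.2) held Prss34 at 0.35 and Fcer1a at 0.26. Haematopoietic progenitor genes (10 measured, adjusted p = 0.926) held Cd34 at -0.30 and Flt3 at -0.23, and stroma and endothelium genes (15 measured, adjusted p = 0.489) held Cdh5 at -0.31 and Dcn at 0.35.

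Of the 37 lists, 11 passed with the preset correlation, 6 higher and 5 lower, and 0 passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Some lists that did not pass were called when 1 mouse was left out: CD8 lineage and cytotoxic effector genes, lower, without PBS replicate 2, cytokines, higher, without PBS replicate 3, inhibitory receptors and autophagy genes, higher, without rapamycin replicate 1, mTOR pathway and macrophage genes, lower, without rapamycin replicate 3, and mast cell genes, higher, without PBS replicate 1 or rapamycin replicate 3. By fry, which tests whether the members of a list move on balance one way, 0 passed and 2 had an unadjusted p under 0.05, with 0.110 as the smallest adjusted p. For changes in either direction fry called 0, with 0.231 as the smallest. The median, mean and test differed in sign for 7 lists: cytotoxic effector, regulatory T cells, oxidative phosphorylation, co-stimulatory receptors, B cells, natural killer cells and haematopoietic progenitors.

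The mice within a group differed from each other, among others in some granulocyte transcripts. The first principal component of the 2000 most variable genes held 40.3% of the variance and did not separate the groups: PBS mice scored -5.80, -8.20 and 4.50, and rapamycin mice -10.6, 10.0 and 10.1. Its negative side was led by the granulocyte genes Retnlg and Mpo, the adhesion molecule Vcam1 and the iron exporter Slc40a1, and its positive side by the immunoglobulin segment Igkv4-91, the enkephalin precursor Penk, Serpinb10 and Nrn1. Retnlg measured 8.17, 8.09 and 5.50 in PBS replicates 1 to 3 and 9.18, 6.02 and 6.80 in rapamycin replicates 1 to 3. The granulocyte score did not follow this component throughout. It was 8.77 in rapamycin replicate 3, which scored 10.1, and 8.60 in PBS replicate 2, which scored -8.20. The second component (22.2%) was led by Penk, Kcnma1, the granzyme Gzmd and the cytokine Il21 on its negative side, and by immunoglobulin kappa segments, Slc40a1 and Spic on its positive side. Over all genes the correlation between arrays was 0.993 to 0.996 within groups and 0.994 to 0.996 between groups.

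**Figure D3:**
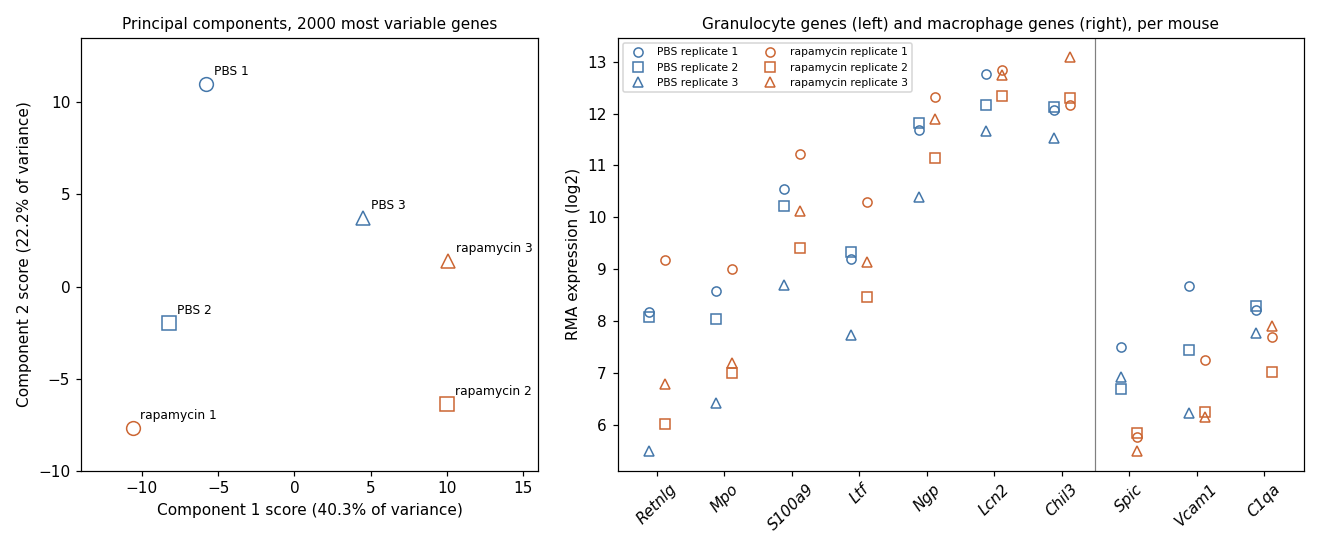
Left, scores of the 6 mice on the first component (x axis, 40.3% of variance) and the second component (y axis, 22.2%), where rapamycin replicate 1 lies at -10.6 on the first component and the other rapamycin mice at 10.0 and 10.1. Right, RMA expression (log2) of granulocyte and macrophage genes in each mouse, blue for PBS and orange for rapamycin; Retnlg spans 5.50 to 9.18 across mice, and Spic does not overlap between the groups.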

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

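The granulocyte score as a covariate was chosen after seeing the data. The count of genes higher with rapamycin was 0 to 6 when each mouse was left out, with 6 only without rapamycin replicate 1, 2 with the granulocyte score (Penk and Scin), 319 at an unadjusted p and 0 otherwise. The count of lower genes was 0 to 1 when each mouse was left out, with 1 only without rapamycin replicate 1. It was 0 with every probe set tested separately, 0 with the plain equal-variance test, 613 at an unadjusted p and 1 otherwise, the block apart. With the replicate block the count was 0 genes and 11 lists, and Glp1r had an adjusted p of 0.151. Same-numbered mice had correlations of their deviations of 0.09, -0.19 and 0.19, and not every mouse correlated best with its own number. These values gave no sign that the numbers pair the mice, but they are too few to exclude it. The count of lists was 7 to 13 when each mouse was left out (7 without rapamycin replicate 2), 18 with the granulocyte score, 0 with an estimated correlation, 0 with fry, 10 without the lowest 50% of genes, 9 with array weights and 11 otherwise. Interferon-stimulated genes had mean differences of -0.176 (without rapamycin replicate 2) to 0.063 (without rapamycin replicate 1, called higher) when each mouse was left out, and 0.049 with the granulocyte score, called higher. Where no cause is named, the cause was not tested. With 3 arrays per group the simulated recovery of 1.5-fold changes was 62.3%, with 200 changed genes per simulation and genes drawn independently. Recovery where few genes change was not simulated, nor were smaller changes, and signal over background was not measured here.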

Other observations

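The tests of rapamycin replicate 1 on 7 genes and on granulocyte genes, those with the correlation of a list set to its estimate and that on list means per mouse were chosen after the result was seen. No granzyme gene passed over all genes. Gzmc differed by 0.53 (SE 0.12), Gzmd by 1.09 (SE 0.46), Gzme by 0.91 (SE 0.38), Gzmf by 1.40 (SE 0.33) and Gzmg by 0.37 (SE 0.08), all related granzymes whose similar sequences leave open how much of each signal belongs to which gene. Gzmb, the main cytotoxic granzyme, differed by -0.01 (SE 0.08), Gzma by -0.05 (SE 0.18), Gzmk by -0.31 (SE 0.14), Gzmm by -0.22 (SE 0.10) and Gzmn by 0.08 (SE 0.11). Penk, the enkephalin precursor, measured 6.89, 7.93 and 8.51 with PBS and 8.72, 10.39 and 9.62 with rapamycin, a difference of 1.80 (SE 0.47, adjusted p = 0.911), and Nrn1 differed by 1.26 (SE 0.31), Plk2 by 1.08 (SE 0.29) and Rgs16 by 0.66 (SE 0.29). These genes were picked after their values were seen.

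Around Glp1r, other genes of its hormone family were measured after the call was seen. Gcg, which encodes the precursor of glucagon and of the ligand of Glp1r, measured 7.88, 9.23 and 10.00 with PBS and 9.28, 10.05 and 9.16 with rapamycin, a difference of 0.46 (SE 0.47). Gipr differed by 0.04, Gcgr by -0.12, Glp2r by -0.04 and Dpp4, the protease that cleaves the ligand, by 0.03. Immunoglobulin kappa segments varied between mice of one group, with a median SD within groups of 0.77 over 8 genes against 0.12 over all genes, T cell receptor alpha variable segments had 0.45 over 6 genes, and immunoglobulin heavy chain segments 0.20 over 4 genes.

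The 10 splits of the 6 mice into groups of 3 are too few for a share under 0.05. For genes the real split gave 1 and the highest other split 1, with 2 splits giving as many. For lists the real split gave 11 and the highest other 20, with 6 splits giving as many. The split that sets PBS replicates 1 and 2 and rapamycin replicate 1 against the rest gave 3197 genes at an unadjusted p under 0.05, against 932 for the real split, so these samples hold a structure that does not follow the treatment.

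Rapamycin replicate 1 lay with PBS replicates 1 and 2 on the first component. Its position was taken on the 100 genes that best separate the other 5 arrays, where 0 is PBS and 1 is rapamycin. The position was 0.35, with 33 genes on the rapamycin side. Resampling the 100 genes gave 0.27 to 0.43, a range that leaves out the spread between mice. Held-out PBS arrays lay at 0.36, 0.51 and 0.43 and the other rapamycin arrays at 0.77 and 0.56. A wrong label of this array therefore stays open. It lay beyond the PBS range on the rapamycin side in 7 of the 7 genes called without it, at a median position of 0.30. Held-out PBS arrays did so in 4, 6 and 6 of the 7 genes with the smallest p without them. Their range came from the remaining PBS arrays and is easier to leave than that of all 3, so the counts are not alike. The count of 7 therefore does not speak against a wrong label. Of the 7 genes called without rapamycin replicate 1, Glp1r and Scin lay past the midpoint on the rapamycin side, and the other 5 lay nearer PBS. The position of this array was 0.82 on Glp1r, against -0.13 to 0.08 in the held-out PBS arrays, and 0.68 on Scin. Granulocyte RNA cannot be told apart from other differences of this mouse. Of 21 granulocyte genes 16 were higher than the mean of rapamycin replicates 2 and 3, with a median difference of 0.72 over all 21. The differences ranged from -0.52 (Chil3) to 2.77 (Retnlg). Sorting for CD3 should remove granulocytes, and sort purity was not measured here. A weaker response to the drug stays open and untested.

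Shifts of the 11 called gene lists were set against members that vary together from mouse to mouse: with each list's correlation set to its estimate 0 of the 9 lists with an estimate above 0.1 stayed called, so shared variation may account for those calls. Homing and adhesion (estimate -0.01) and fatty acid synthesis (0.02) stayed called, 2 of 2, at adjusted p of 9.16e-06 and 0.00174. Their estimates lie near the preset 0.01, so this nearly repeats the preset test and decides little. They did not stay called when the uncertainty of the estimate was taken in (0.248 and 0.323) nor by fry. Shared variation thus stays open for them, beside an effect of rapamycin as a hypothesis. With the granulocyte score as a covariate the differences of means per mouse of these lists were -0.18 (95% interval -0.28 to -0.08) and -0.15 (-0.24 to -0.07). Without it they were -0.19 and -0.15. This adjustment decides little, since lists picked for a low correlation vary little within a group and leave the score little to take up. The score overlapped between the groups, at 7.89 to 8.98 with PBS and 8.35 to 9.25 with rapamycin, where these list means did not. As far as the score tracks it, that argues against granulocyte RNA as the whole cause for these lists, 2 of 2. For the other 8 lists granulocyte RNA cannot be told apart. Before the score 0 of 8 had an interval without 0, and with it 1 of 8 (mitosis). Under camera 9 of the 10 lists stayed called with the score, sterol biosynthesis excepted, but 9 further lists became called, and that test called 33.8% of simulated lists that had correlated members and no shift, so staying called decides little.

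Spic was lower in every rapamycin mouse than in every PBS mouse but did not pass over all genes. Fewer red pulp macrophages in the sorted cells would lower their other markers too, and 12 of 14 such markers had negative differences, with a median of -0.43, Vcam1 at -0.90 (SE 0.54) and Slc40a1 at -1.01 (SE 0.57), although sorting for CD3 should remove these cells. With the mean of these markers as a covariate the Spic difference was -1.17 (SE 0.24, 95% interval -1.72 to -0.62), against -1.34 without it. The mean of these markers thus carried little of the Spic difference. Fewer red pulp macrophages stay open, since such a mean tracks these cells with error and may adjust too little. With the granulocyte score the Spic difference was -1.41 (95% interval -1.89 to -0.93). PBS replicate 1 had a higher score (8.98) than rapamycin replicates 2 and 3 (8.35 and 8.77), yet more Spic (7.51 against 5.84 and 5.50). This argues against granulocyte RNA as far as the score tracks it. Less Spic RNA in the cells that carry it stays a hypothesis that was not tested.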
